A study of Mus musculus with 13 samples.

How the data were processed

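Bulk RNA-seq was made from total RNA of 13 whole-liver samples from male C57BL/6 mice, per the labels. They fell into 4 groups by diet and AAV9 cargo: 3 control-diet (NCD) EGFP, 3 control-diet hDC-SIGN, 3 HFHC EGFP and 4 HFHC hDC-SIGN samples. Diets lasted 16 weeks, with injection after 8 weeks.

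The authors deposited an expected count and an FPKM value per gene and sample, per the file headers. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.3.4.3, RSEM 1.3.1 and the GRCm38 build, without the role or order of each. The annotation version and strand setting are not stated in the notes used here, so genes that overlap or lie antisense to a neighbour cannot be told apart. About 5% of the deposited counts are not whole, as estimated counts are, and they were rounded for the tests. The deposited FPKM values were not used in any test. All 26 value columns were matched to samples, and the groups were taken from the sample titles.

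The table held 17161 genes, 484 of them without a count, and 8 symbols had been turned into dates. Gene IDs matched a GRCm38.p6 reference for 17112 genes, and coordinates are from that reference, counted from 1. Estimated counts summed to 17532139 to 18599790 per library. Precision for scarce transcripts is limited at this depth, and total counts are given for named genes with fewer than 20 counts in a group compared.

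Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 12619. Counts were scaled by TMM factors and fitted with edgeR 4.0.16 in R 4.3.3, with all 4 groups in 1 quasi-likelihood fit without covariates. Tests were 2-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The 5 comparisons were diet with EGFP, hDC-SIGN on the HFHC diet, hDC-SIGN on the control diet, diet with hDC-SIGN, and the interaction of diet and vector. A standard error is the absolute log2 fold change divided by the square root of the test's F. CPM values are scaled by TMM and given as mean ± SD over 3 or 4 samples, and a value in parentheses after a gene, or after "changed by", is its log2 fold change ± SE.

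Of 38 gene lists, 34 had at least 3 tested genes. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera was also run with the correlation estimated from the data, and members were counted both over all genes and adjusted over the list alone. Fry, a rotation test of whether a list's genes move 1 way, gave another reading. The groups, tests, lists and rule for naming genes were chosen before the data were examined. The rule takes, per comparison, up to 10 genes with the largest changes in each direction (5 for the interaction) with at least 2 CPM in the higher group. For the comparisons other than the interaction it also asks for no overlap between replicates. It adds up to 4 members per list with the smallest adjusted p, or up to 2 with the smallest p where none passed, and all measured mouse Cd209 genes.

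The method was tested on simulated counts with 200 genes changed. For hDC-SIGN on the HFHC diet it recovered 35.8%, 71.6% and 97% of genes changed by 1.5, 2 and 4-fold among 12422 genes, with 6.2% of calls false. For hDC-SIGN on the control diet these were 34.3%, 82.1% and 95.5% among 12422 genes, with 6.6% false. Diet with EGFP gave 47.8%, 77.6% and 98.5% among 12426 genes, with 5.7% false, and diet with hDC-SIGN 43.3%, 71.6% and 93.9% among 12429 genes, with 2.8% false. The interaction gave 19.4%, 52.2% and 81.8% among 12428 genes, with 3.8% false.

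Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals, no filter, a filter of 1 CPM in 3 samples, robust empirical Bayes, a 2-fold threshold, only the 2 groups compared, the replicate number of the titles or of the file columns as a block, and leaving out each library. The correlation of the diet and vector effects was set beside 100 simulated data sets in which no group differed. Near-identical gene copies, such as the Mup, Serpina1, Cyp2 and Saa families, may share reads, so their values are uncertain. Figures were drawn with Python 3.11.15.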

Results

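Liver RNA was profiled in 13 samples from male C57BL/6 mice after 16 weeks on the HFHC diet or on a control diet (NCD). After the first 8 weeks, mice received by tail vein an AAV9 virus whose name carries CD68, a macrophage gene, and either EGFP, a fluorescent protein used as the control cargo, or hDC-SIGN, human CD209, a C-type lectin of dendritic cells and macrophages. Livers were taken 8 weeks later. The groups held 3 control-diet EGFP, 3 control-diet hDC-SIGN, 3 HFHC EGFP and 4 HFHC hDC-SIGN samples, each called a liver below. Estimated counts summed to 17532139 to 18599790 per library, and 14388 to 15117 genes had a count. The labels do not state that each sample is a separate mouse, so p-values measure the spread between these samples, which may be technical.

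The first principal component held 44.1% of the variance and placed the 3 HFHC EGFP livers at 44.2 to 57.6, the control-diet livers at -35.4 to -20.1 and the HFHC hDC-SIGN livers at -3.7 to 7.7. The second component held 17.1% and placed the HFHC hDC-SIGN livers at 24.7 to 31.1, above every other library. Mouse genes for CD209 relatives were mostly near the floor, and Cd209c was the 1 of 6 in the table with enough counts to test. Human DC-SIGN and EGFP are not among the genes of this mouse table, so the vector labels have no check from the transgene.

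**Figure D1:**
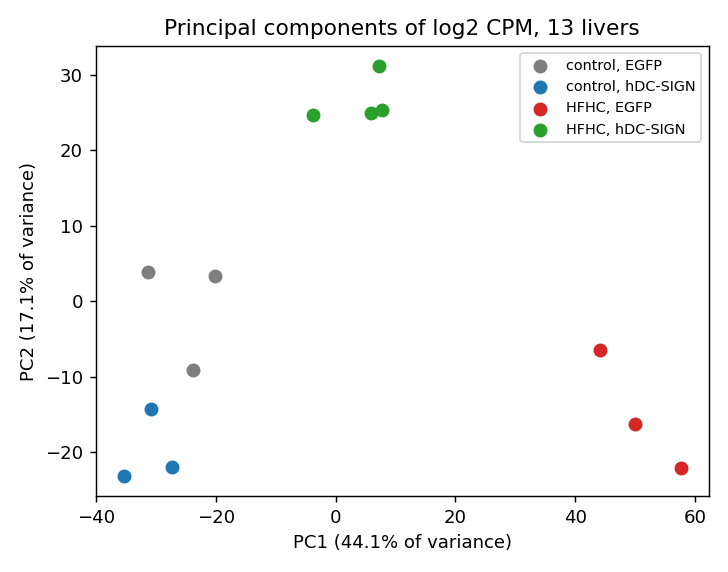
First against second principal component of log2 CPM (arbitrary units, with the share of variance on each axis) for 13 livers, 1 point per library, coloured by group. The HFHC EGFP livers lie at 44.2 or above on the first axis and the HFHC hDC-SIGN livers at 7.7 or below.

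The first comparison set the HFHC diet against the control diet in mice given the EGFP vector. Gpnmb, a glycoprotein of lipid-laden macrophages (gene ID 93695, chromosome 6, 49036518 to 49058182 on GRCm38), rose to 24.9 ± 10.1 CPM (SD, n = 3) from 0.0785 ± 0.0342 CPM (SD, n = 3), a log2 fold change of 8.19 ± 0.56 (SE) that is imprecise because the control-diet livers had 4 counts in all. Lgals3 rose from 3.37 ± 0.938 to 22.6 ± 5.98 CPM (log2 fold change 2.75 ± 0.22), and Clec7a, a receptor for fungal glucans, from 2.12 ± 0.241 to 15.7 ± 4.52 CPM (2.89 ± 0.22). Col1a2, a collagen chain, Cidea, a lipid droplet protein, and Srebf1, a regulator of fatty acid synthesis, also rose. Hsd3b5, a male-biased hydroxysteroid dehydrogenase, and Ehhadh, an enzyme of fatty acid oxidation, fell.

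Of 12619 genes tested, 5178 changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2700 up and 2478 down, and 1436 of them changed at least 2-fold, 1195 up and 241 down. With libraries scaled by their totals alone, 90.4% of 6110 calls were higher against 52.1% here, and that scaling moved the median of all genes by 0.28 on the log2 scale. Under that scaling 18 lists were called, 10 up and 8 down, against 23 here, 17 up and 6 down, and the calls of Kupffer, alternatively activated macrophage, neutrophil, sinusoidal endothelial, stellate, interferon-stimulated and cell cycle lists were lost.

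Monocyte-derived and lipid-associated macrophage markers had the highest median of the 34 tested lists, 2.89. There, 14 of 15 tested members rose (14 up and 0 down adjusted over the list alone, camera adjusted p = 7.6e-20, adjusted p = 0.0244 with an estimated correlation). This list's calls for the diet in EGFP livers and for hDC-SIGN on the HFHC diet are the 2 list calls that hold with an estimated correlation in any of the 5 comparisons. For class II antigen presentation, 8 of 8 tested members rose (8 up and 0 down adjusted over the list alone, camera adjusted p = 1.14e-12, adjusted p = 0.145 with an estimated correlation). H2-Aa, a class II chain, went from 18.4 ± 4.66 to 81.1 ± 14.3 CPM (2.14 ± 0.22, edgeR adjusted p = 3.54e-05). For Kupffer cell markers, of 12 tested members, 7 rose and 2 fell (8 up and 3 down adjusted over the list alone, camera adjusted p = 0.0188, adjusted p = 0.501 with an estimated correlation). C1qb and Cd5l rose by 1.17 and 1.33 on the log2 scale, while C6, a complement gene that hepatocytes also express, fell by 1.32. For dendritic cell markers, 5 of 6 tested members rose (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.00793, adjusted p = 0.23 with an estimated correlation). Irf8 changed by 1.22 ± 0.17. For neutrophil markers, 4 of 5 tested members rose (4 up and 0 down adjusted over the list alone, camera adjusted p = 0.0153, adjusted p = 0.392 with an estimated correlation). Csf3r changed by 1.24 ± 0.18. In alternatively activated macrophage genes, 2 of 5 tested members rose (2 up and 0 down adjusted over the list alone, camera adjusted p = 0.0354, adjusted p = 0.392 with an estimated correlation). For chemokines, of 12 tested members, 7 rose and 1 fell (7 up and 1 down adjusted over the list alone, camera adjusted p = 0.00073, adjusted p = 0.23 with an estimated correlation). Ccl6 changed by 1.64 ± 0.15 and Cxcl16 by 1.48 ± 0.15. Among TLR, NF-kB and inflammasome genes, of 14 tested members, 10 rose and 1 fell (11 up and 1 down adjusted over the list alone, camera adjusted p = 0.00793, adjusted p = 0.23 with an estimated correlation). Tlr2 changed by 1.86 ± 0.25 and Nfkbia by -0.69 ± 0.11. For interferon-stimulated genes, 6 of 18 tested members rose (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.0354, adjusted p = 0.559 with an estimated correlation). Bst2 went from 90.1 ± 4.74 to 127 ± 11.2 CPM.

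In the matrix list, 13 of 17 tested members rose (13 up and 0 down adjusted over the list alone, camera adjusted p = 2.35e-06, adjusted p = 0.23 with an estimated correlation). Col1a2 rose to 53.7 ± 7.51 CPM from 11 ± 2.41 (2.28 ± 0.31, edgeR adjusted p = 0.000153). For stellate cell markers, 6 of 10 tested members rose (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.0326, adjusted p = 0.474 with an estimated correlation). Pdgfrb changed by 1.41 ± 0.18. For endothelial markers of the sinusoid, 7 of 10 tested members rose (7 up and 0 down adjusted over the list alone, camera adjusted p = 0.0188, adjusted p = 0.501 with an estimated correlation). Stab2 went from 28.6 ± 2.69 to 46.5 ± 14.7 CPM. The rise was uneven among livers: Oit3 stood at 20.24, 29.95 and 10.75 CPM in HFHC EGFP replicates 1 to 3. Its control-diet EGFP range was 12.77 to 15.6 CPM. Replicate 3 also lay within or below that group's range for Kdr, Pecam1 and Gpr182, but above it for Stab1, Stab2, Lyve1 and Cdh5. For cell cycle genes, 5 of 9 tested members rose (5 up and 0 down adjusted over the list alone, camera adjusted p = 0.00793, adjusted p = 0.23 with an estimated correlation). The proliferation gene Mki67 changed by 2.09 ± 0.27.

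Metabolic lists went in both directions. In lipogenesis, of 19 tested members, 11 rose and 1 fell (11 up and 1 down adjusted over the list alone, camera adjusted p = 1.72e-05, adjusted p = 0.23 with an estimated correlation). Srebf1 rose from 46.9 ± 10.5 to 361 ± 55.7 CPM (2.94 ± 0.21) and Scd1, a fatty acid desaturase, from 2670 ± 1330 to 20000 ± 944 CPM. For targets of LXR, a sterol-sensing receptor, 7 of 8 tested members rose (7 up and 0 down adjusted over the list alone, camera adjusted p = 0.000338, adjusted p = 0.206 with an estimated correlation). Abcg1 changed by 1.95 ± 0.21. In the lipid droplet list, of 12 tested members, 8 rose and 1 fell (8 up and 1 down adjusted over the list alone, camera adjusted p = 0.00248, adjusted p = 0.356 with an estimated correlation). Cidea went from 1.54 ± 1.93 to 158 ± 59 CPM, with 64, 14 and 1 counts in control-diet EGFP replicates 1 to 3. Adipocyte markers were uneven in these control-diet livers too. Cfd had 121, 8 and 2 counts, and Adipoq had 26 in all, 24 of them in 1 library. For NRF2 targets, of 11 tested members, 7 rose and 1 fell (7 up and 1 down adjusted over the list alone, camera adjusted p = 0.00269, adjusted p = 0.334 with an estimated correlation). Srxn1 changed by 1.23 ± 0.16. For cholesterol synthesis, of 21 tested members, 1 rose and 9 fell (1 up and 9 down adjusted over the list alone, camera adjusted p = 0.00824, adjusted p = 0.559 with an estimated correlation). Cyp51 changed by -1.98 ± 0.35. For fatty acid oxidation, of 19 tested members, 1 rose and 9 fell (1 up and 9 down adjusted over the list alone, camera adjusted p = 0.00821, adjusted p = 0.509 with an estimated correlation). Ehhadh changed by -1.23 ± 0.25. Among ER stress genes, of 13 tested members, 1 rose and 8 fell (1 up and 10 down adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.453 with an estimated correlation). Herpud1 changed by -1.35 ± 0.17, and Chac1, a glutathione-degrading enzyme, by 2.04 ± 0.23. Among bile acid genes, of 15 tested members, 1 rose and 6 fell (1 up and 6 down adjusted over the list alone, camera adjusted p = 0.0354, adjusted p = 0.392 with an estimated correlation). Cyp7b1 went from 563 ± 334 to 53.9 ± 22.1 CPM. Among periportal hepatocyte genes, 5 of 9 tested members fell (0 up and 6 down adjusted over the list alone, camera adjusted p = 0.00801, adjusted p = 0.392 with an estimated correlation). Among male-biased genes, 6 of 8 tested members fell (0 up and 6 down adjusted over the list alone, camera adjusted p = 0.000565, adjusted p = 0.23 with an estimated correlation). Hsd3b5 fell from 115 ± 64.2 to 1.08 ± 1.19 CPM (-6.73 ± 0.74), while female-biased Cyp2a4 rose from 0.334 ± 0.171 CPM, 17 counts in all, to 30 ± 25.8 CPM. Hsd3b5, Cyp2a4, Cyp2b9, the Mup genes and Serpina1e have close copies, so their counts are uncertain.

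**Figure D2:**
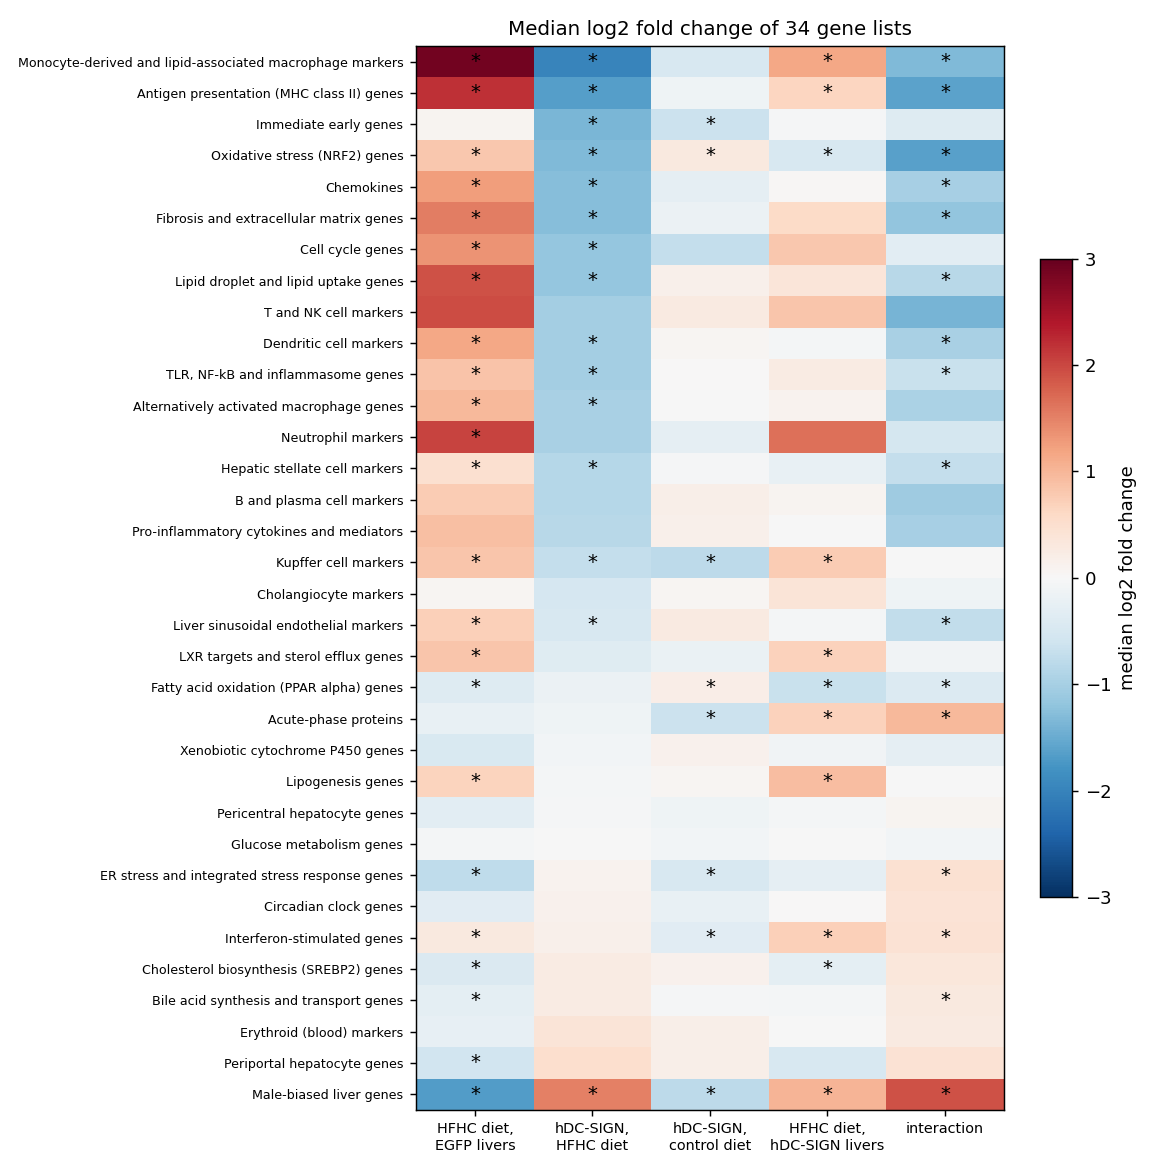
Median log2 fold change (colour, from -3 to 3) of the tested members of 34 gene lists (vertical axis) in 5 comparisons (horizontal axis); an asterisk marks a camera adjusted p under 0.05 with the preset correlation. The monocyte-derived and lipid-associated macrophage list has a median of 2.89 for diet in EGFP livers and -1.97 for hDC-SIGN on the HFHC diet.

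The second comparison, the one the series title centres on, set hDC-SIGN against EGFP in mice on the HFHC diet. Gpnmb fell from 24.9 ± 10.1 CPM (SD, n = 3) to 0.639 ± 0.328 CPM (SD, n = 4), a log2 fold change of -5.27 ± 0.36 (SE), and Mmp12, a macrophage elastase, from 17.2 ± 4.61 to 0.413 ± 0.278 CPM (-5.36 ± 0.35). H2-Aa of antigen presentation, Col1a2, the stellate cell gene Dcn and the chemokine Ccl2 also fell. Male-biased Hsd3b5 rose from 1.08 ± 1.19 to 158 ± 42.2 CPM (SD, n = 4). Of 19 lipogenesis genes 1 passed the threshold, and Srebf1 stood at 361 ± 55.7 and 339 ± 79.4 CPM. Other members were not flat. Scd1 did not pass but lay lower without overlap, at 8857 to 16690 CPM with hDC-SIGN against 19030 to 20890 CPM with EGFP. Mlxipl lay higher without overlap, at 423.4 to 484.7 against 250.6 to 351.4 CPM.

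By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2931 of 12619 genes changed, 1202 up and 1729 down, and 894 changed at least 2-fold, 167 up and 727 down. Scaling by library totals gave 4254 calls, 9% of them higher against 41% here, and moved the median gene by -0.21 on the log2 scale; it called 17 lists, 4 up and 13 down, against 15 here, 1 up and 14 down, and the call of sinusoidal endothelial markers was lost. Without HFHC EGFP replicate 2, 1614 genes passed.

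In the monocyte-derived and lipid-associated macrophage list, 12 of 15 tested members fell (1 up and 14 down adjusted over the list alone, camera adjusted p = 1.09e-24, adjusted p = 0.0133 with an estimated correlation). For class II antigen presentation, 8 of 8 tested members fell (0 up and 8 down adjusted over the list alone, camera adjusted p = 2.1e-14, adjusted p = 0.0772 with an estimated correlation). H2-Aa went from 81.1 ± 14.3 to 25.5 ± 4.97 CPM (-1.67 ± 0.19). For Kupffer cell markers the median was -0.72, against -1.97 for the monocyte-derived and lipid-associated list. There, of 12 tested members, 1 rose and 7 fell (2 up and 7 down adjusted over the list alone, camera adjusted p = 0.00192, adjusted p = 0.474 with an estimated correlation). Cd5l changed by -1.28 ± 0.18 and C1qb by -1.05 ± 0.13, while C6 changed by 1.3 ± 0.18. In the alternatively activated list, 3 of 5 tested members fell (0 up and 3 down adjusted over the list alone, camera adjusted p = 0.00694, adjusted p = 0.271 with an estimated correlation). Tgfb1 changed by -1.19 ± 0.17. For dendritic cell markers, 3 of 6 tested members fell (0 up and 5 down adjusted over the list alone, camera adjusted p = 0.00349, adjusted p = 0.139 with an estimated correlation). Neutrophil markers were not called as a list, and 1 of 5 tested members fell (0 up and 2 down adjusted over the list alone, camera adjusted p = 0.0544, adjusted p = 0.552 with an estimated correlation). For chemokines, of 12 tested members, 1 rose and 8 fell (1 up and 9 down adjusted over the list alone, camera adjusted p = 9.39e-08, adjusted p = 0.0772 with an estimated correlation). Ccl2, which attracts monocytes, fell from 2.11 ± 0.488 to 0.213 ± 0.0862 CPM, 15 counts in all (-3.27 ± 0.43, edgeR adjusted p = 0.000328). HFHC hDC-SIGN replicate 2 lay apart at 0.343 CPM, from 6 counts against 3 in each of the others. For TLR, NF-kB and inflammasome genes, of 14 tested members, 1 rose and 10 fell (2 up and 12 down adjusted over the list alone, camera adjusted p = 0.000261, adjusted p = 0.113 with an estimated correlation). Tlr2 changed by -1.24 ± 0.21. Of 14 cytokine and mediator genes, 3 had enough counts to test, and Il1b fell from 1.84 ± 0.313 to 0.796 ± 0.269 CPM (-1.21 ± 0.31, edgeR adjusted p = 0.0133), a call lost without HFHC EGFP replicate 2. Tnf, named here after its values were seen, had 19 counts in all in the 3 HFHC EGFP livers and 5 in the 4 HFHC hDC-SIGN livers, so a difference was not tested at this depth, and Il6 had 0 counts in every group.

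In the matrix list, of 17 tested members, 1 rose and 12 fell (1 up and 13 down adjusted over the list alone, camera adjusted p = 5.72e-09, adjusted p = 0.113 with an estimated correlation). Col1a2 went from 53.7 ± 7.51 to 13.9 ± 6.45 CPM (-1.94 ± 0.27) and Fbn1 fell by 1.73. For stellate cell markers, 9 of 10 tested members fell (0 up and 9 down adjusted over the list alone, camera adjusted p = 9.51e-07, adjusted p = 0.113 with an estimated correlation). Dcn changed by -0.89 ± 0.12. For sinusoidal endothelial markers, 4 of 10 tested members fell (0 up and 6 down adjusted over the list alone, camera adjusted p = 0.0323, adjusted p = 0.566 with an estimated correlation). Lyve1 changed by -1.61 ± 0.35, with HFHC hDC-SIGN replicate 3 apart at 9.5 CPM. For cell cycle genes, 5 of 9 tested members fell (0 up and 5 down adjusted over the list alone, camera adjusted p = 0.000803, adjusted p = 0.113 with an estimated correlation). Mki67 changed by -2.1 ± 0.24. Among immediate early genes, of 11 tested members, 1 rose and 5 fell (1 up and 8 down adjusted over the list alone, camera adjusted p = 0.00018, adjusted p = 0.113 with an estimated correlation). Jun went from 53.7 ± 0.183 to 19.7 ± 6.56 CPM. Among NRF2 targets, 8 of 11 tested members fell (0 up and 8 down adjusted over the list alone, camera adjusted p = 1.97e-08, adjusted p = 0.0772 with an estimated correlation). Hmox1, a heme-degrading enzyme, changed by -1.46 ± 0.17. For lipid droplet genes, 6 of 12 tested members fell (0 up and 6 down adjusted over the list alone, camera adjusted p = 4.33e-05, adjusted p = 0.149 with an estimated correlation). Vldlr, a lipoprotein receptor, changed by -2.47 ± 0.24 and Pparg by -0.87 ± 0.18. In lipogenesis, 1 of 19 tested members rose (1 up and 0 down adjusted over the list alone, camera adjusted p = 0.653, adjusted p = 0.875 with an estimated correlation). At an unadjusted p under 0.05 by edgeR there were 5 members, and DESeq2 called 2. The median of this list was -0.07 while its mean and test had the positive sign. Among male-biased genes, 5 of 8 tested members rose (5 up and 0 down adjusted over the list alone, camera adjusted p = 9.2e-06, adjusted p = 0.0984 with an estimated correlation). Slco1a1, a hepatocyte uptake transporter, went from 48.9 ± 26.6 to 323 ± 71.5 CPM (2.72 ± 0.32). Both tested female-biased genes fell, Cyp2b9 by 5.71 and Cyp2a4 by 5.6 on the log2 scale. Mup genes took 3.08% to 4.01% of counts in the HFHC EGFP livers and 8.3% to 13.01% in the HFHC hDC-SIGN livers. Nr1h3, the gene of the receptor LXR alpha, was called higher at 0.18 ± 0.06, and turned to -0.02 under library totals.

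**Figure D3:**
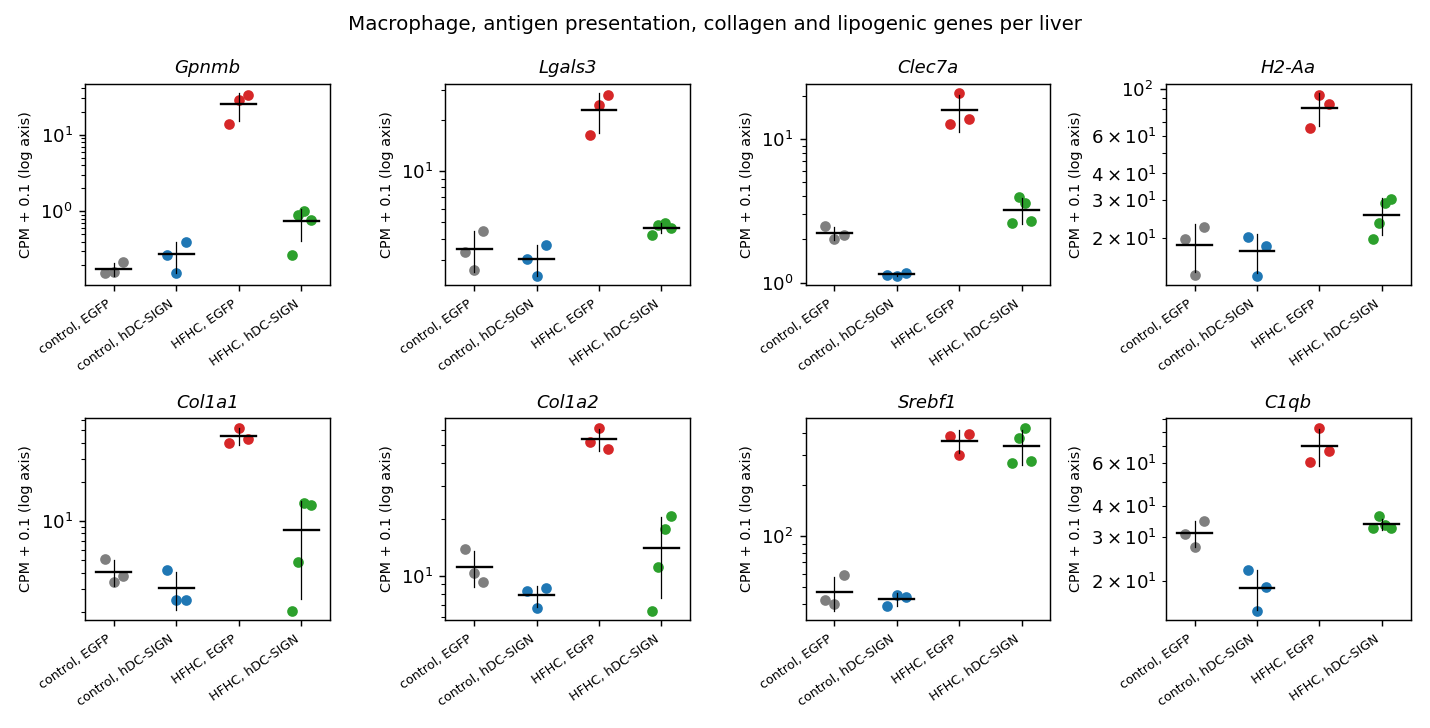
CPM plus 0.1 on a log axis for 8 genes in 13 livers, 1 point per library; horizontal lines give group means and vertical lines 1 SD on either side, stopped at 0. Gpnmb lay at 24.9 ± 10.1 CPM (mean ± SD) in HFHC EGFP livers and 0.639 ± 0.328 CPM in HFHC hDC-SIGN livers, while Srebf1 lay at 361 ± 55.7 and 339 ± 79.4 CPM.

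Diet and vector effects on the HFHC diet ran in opposite directions across genes. Of the 2700 genes that rose with the diet in EGFP livers, 1360, or 50.4%, fell with hDC-SIGN, where independent lists would share 369.9. Of the 2478 that fell with the diet, 733, or 29.6%, rose with hDC-SIGN, where independent lists would share 236. The same direction was found for 25 genes up in both and 20 down in both. Pearson's r across genes was -0.78, and genes are not independent replicates. Both comparisons use the 3 HFHC EGFP libraries, which favours opposite directions, so independent lists are not a fair reference for these overlaps. Unchanged simulated groups gave a mean r of -0.52 (range -0.54 to -0.48). Opposite signs were found for 75.8% of all genes, against 67.4% in those simulations. The covariance was -0.3 against a simulated -0.025, a difference of -0.274. The simulations shared the same 3 libraries, so the excess is beyond what sharing gave there. They drew each gene independently, so deviations common to many genes in the shared livers are not covered. Part of the excess may still come from these, and a division of the shared libraries was not run.

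**Figure D4:**
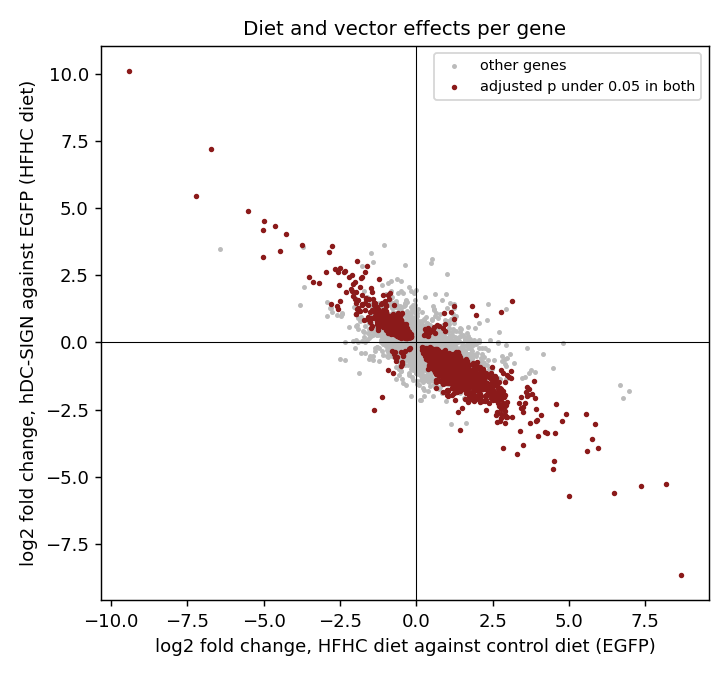
Log2 fold change of the HFHC diet in EGFP livers (horizontal axis) against that of hDC-SIGN on the HFHC diet (vertical axis), 1 point per gene for 12619 genes, with genes past the threshold in both in dark red. Most dark red points lie in the lower right (1360 genes) and upper left (733 genes).

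The third comparison asked what hDC-SIGN changed on the control diet. Saa1, an acute-phase serum amyloid (gene ID 20208, chromosome 7, 46740497 to 46743181 on GRCm38), fell from 524 ± 359 CPM (SD, n = 3) with EGFP to 16.1 ± 5.34 CPM (SD, n = 3) with hDC-SIGN, a log2 fold change of -5.02 ± 0.97 (SE), and Orm2, an orosomucoid, from 79.2 ± 28.3 to 7.6 ± 3.54 CPM (-3.38 ± 0.45). EGFP replicate 3 lay nearer to the hDC-SIGN livers than replicates 1 and 2 for Saa1 (109 CPM against 714.8 and 746.9), Hsd3b5 (46.18 against 124.4 and 173.4) and Cyp7b1 (229.7 against 562.1 and 896.9). Male-biased Hsd3b5 fell from 115 ± 64.2 to 10.4 ± 6.11 CPM and female-biased Cyp2b9 rose from 1.21 ± 0.439 to 15 ± 12.7 CPM. The complement gene C1qb of Kupffer cells fell, and Cd209c, a mouse relative of DC-SIGN, rose from 2.84 ± 0.571 to 8.19 ± 2.71 CPM (1.53 ± 0.37, edgeR adjusted p = 0.0478). Saa1 and Saa2, Orm1 and Orm2, and the Cd209 genes are near copies of each other, so their counts are uncertain.

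By the same edgeR test, 305 of 12619 genes changed, 140 up and 165 down, and 73 changed at least 2-fold, 20 up and 53 down. DESeq2 gave 661 changed genes, 269 up and 392 down, and a block by the file's column numbers, chosen after seeing the data, gave 59. Under library totals 66.9% of 393 calls were higher, against 45.9%. This count was unstable when single libraries were left out: it was 9, 17 and 175 without hDC-SIGN replicates 1, 2 and 3. It was 186, 23 and 416 without EGFP replicates 1, 2 and 3, 163 without HFHC EGFP replicate 3 and 176 without HFHC hDC-SIGN replicate 3. Fewer livers also lower the power, which was not separated from the effect of a given liver. Without control-diet hDC-SIGN replicate 1, each gene named for this comparison lost its call, and each except Orm2 also lost it without at least 1 other library.

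For acute-phase proteins, 5 of 14 tested members fell (0 up and 9 down adjusted over the list alone, camera adjusted p = 3.93e-11, adjusted p = 0.342 with an estimated correlation). Hpx, which binds heme, went from 6320 ± 498 to 3610 ± 165 CPM (-0.81 ± 0.14). For Kupffer cell markers, 4 of 12 tested members fell (0 up and 10 down adjusted over the list alone, camera adjusted p = 3.93e-11, adjusted p = 0.333 with an estimated correlation). C1qb changed by -0.74 ± 0.14, Cd5l by -0.82 ± 0.19 and Folr2 by -0.99 ± 0.22. Among male-biased genes, 2 of 8 tested members fell (0 up and 6 down adjusted over the list alone, camera adjusted p = 1.35e-06, adjusted p = 0.307 with an estimated correlation). They were Hsd3b5 and Ugt2b38 (-3.86 ± 0.72). Camera called 5 more lists without a member past the all-gene threshold. In interferon-stimulated genes 0 of 18 tested members passed by edgeR, 6 at an unadjusted p under 0.05 and 3 by DESeq2 (0 up and 2 down adjusted over the list alone, camera adjusted p = 0.00304, adjusted p = 0.838 with an estimated correlation). In ER stress genes, 0 of 13 tested members passed by edgeR, 5 at an unadjusted p under 0.05 and 4 by DESeq2 (0 up and 4 down adjusted over the list alone, camera adjusted p = 0.0053, adjusted p = 0.831 with an estimated correlation). In immediate early genes 0 of 11 tested members passed by edgeR, 7 at an unadjusted p under 0.05 and 2 by DESeq2 (0 up and 4 down adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.428 with an estimated correlation). In fatty acid oxidation, 0 of 19 tested members passed by edgeR, 5 at an unadjusted p under 0.05 and 0 by DESeq2 (1 up and 0 down adjusted over the list alone, camera adjusted p = 0.00744, adjusted p = 0.838 with an estimated correlation). In NRF2 targets, 0 of 11 tested members passed by edgeR, 3 at an unadjusted p under 0.05 and 1 by DESeq2 (2 up and 0 down adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.823 with an estimated correlation). For monocyte-derived and lipid-associated macrophage markers, 0 of 15 tested members passed by edgeR, 4 at an unadjusted p under 0.05 and 3 by DESeq2 (0 up and 3 down adjusted over the list alone, camera adjusted p = 0.0702, adjusted p = 0.838 with an estimated correlation). For class II antigen presentation, 0 of 8 tested members passed by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2 (0 up and 0 down adjusted over the list alone, camera adjusted p = 0.438, adjusted p = 0.838 with an estimated correlation). For the matrix list, 0 of 17 tested members passed by edgeR, 4 at an unadjusted p under 0.05 and 0 by DESeq2 (0 up and 0 down adjusted over the list alone, camera adjusted p = 0.166, adjusted p = 0.838 with an estimated correlation). For bile acid genes, 2 of 15 tested members fell (0 up and 2 down adjusted over the list alone, camera adjusted p = 0.129, adjusted p = 0.838 with an estimated correlation), with a median of -0.03. These were Cyp7b1, which fell from 563 ± 334 to 136 ± 11.6 CPM (-2.05 ± 0.42), and Cyp2c70 (-1.75 ± 0.29). Gadd45b, a stress-response gene, rose from 4.99 ± 1.43 to 14.2 ± 3.4 CPM (1.51 ± 0.31), and Cish, a cytokine signalling inhibitor, from 5.26 ± 1.88 to 13.2 ± 3.26 CPM (1.33 ± 0.32).

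**Figure D5:**
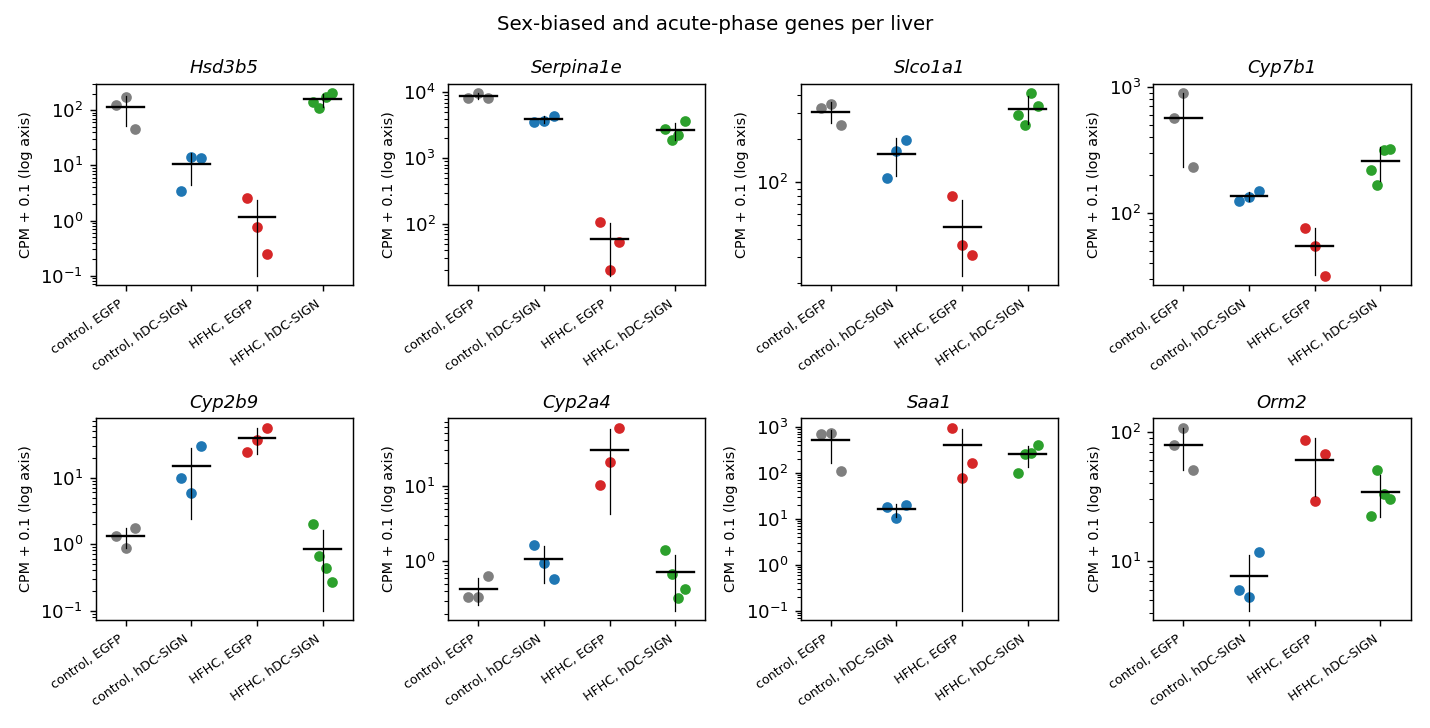
CPM plus 0.1 on a log axis for 8 genes in 13 livers, 1 point per library; horizontal lines give group means and vertical lines 1 SD on either side, stopped at 0. Hsd3b5 lay at 115 ± 64.2, 10.4 ± 6.11, 1.08 ± 1.19 and 158 ± 42.2 CPM (mean ± SD) in the groups from left to right.

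The fourth comparison set the HFHC diet against the control diet in mice given hDC-SIGN. Srebf1 rose from 42.5 ± 3.48 to 339 ± 79.4 CPM (SD, n = 4), a log2 fold change of 3 ± 0.2 (SE), and Thrsp, a lipogenic regulator, from 11.7 ± 3.38 to 317 ± 100 CPM (4.75 ± 0.48). Ehhadh fell from 2970 ± 726 to 552 ± 88.8 CPM (-2.43 ± 0.24) and Pdk4, a kinase that spares glucose, from 41.8 ± 12 to 4 ± 1.5 CPM. Oas1a, an interferon-stimulated gene, and Fga, a fibrinogen chain, rose.

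The edgeR test called 3123 of 12619 genes, 1635 up and 1488 down, with 606 at least 2-fold changed, 456 up and 150 down. Without control-diet hDC-SIGN replicates 1 or 2 the count was 1948 or 1787. The diet effect here and in EGFP livers shares no library; r across genes was 0.39, 821 genes rose in both and 893 fell in both, where independent lists would share 349.8 and 292.2.

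In lipogenesis, of 19 tested members, 14 rose and 2 fell (14 up and 2 down adjusted over the list alone, camera adjusted p = 6.77e-10, adjusted p = 0.292 with an estimated correlation). For fatty acid oxidation, 13 of 19 tested members fell (0 up and 13 down adjusted over the list alone, camera adjusted p = 2.39e-13, adjusted p = 0.343 with an estimated correlation). For cholesterol synthesis, 6 of 21 tested members fell (0 up and 6 down adjusted over the list alone, camera adjusted p = 0.0259, adjusted p = 0.893 with an estimated correlation). Hmgcs1 changed by -0.99 ± 0.22. For LXR targets, 5 of 8 tested members rose (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.000128, adjusted p = 0.292 with an estimated correlation). Abca1 changed by 0.88 ± 0.09. For interferon-stimulated genes, 11 of 18 tested members rose (14 up and 0 down adjusted over the list alone, camera adjusted p = 3.14e-08, adjusted p = 0.365 with an estimated correlation). Oas1a changed by 1.8 ± 0.23. For acute-phase proteins, 10 of 14 tested members rose (13 up and 0 down adjusted over the list alone, camera adjusted p = 7.24e-07, adjusted p = 0.365 with an estimated correlation). Fga changed by 0.67 ± 0.13. Among Kupffer cell markers, 8 of 12 tested members rose (10 up and 0 down adjusted over the list alone, camera adjusted p = 1.35e-05, adjusted p = 0.365 with an estimated correlation). Folr2 changed by 1.33 ± 0.21. For monocyte-derived and lipid-associated macrophage markers, 7 of 15 tested members rose (11 up and 0 down adjusted over the list alone, camera adjusted p = 4.19e-05, adjusted p = 0.343 with an estimated correlation). Clec7a went from 1.04 ± 0.026 to 3.1 ± 0.66 CPM. Among class II genes, 3 of 8 tested members rose (8 up and 0 down adjusted over the list alone, camera adjusted p = 0.00833, adjusted p = 0.644 with an estimated correlation). For NRF2 targets, 5 of 11 tested members fell (0 up and 6 down adjusted over the list alone, camera adjusted p = 0.00363, adjusted p = 0.365 with an estimated correlation). For male-biased genes, 5 of 8 tested members rose (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.00446, adjusted p = 0.365 with an estimated correlation). In the matrix list, 3 of 17 tested members rose (2 up and 0 down adjusted over the list alone, camera adjusted p = 0.0769, adjusted p = 0.874 with an estimated correlation).

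The interaction tested whether the hDC-SIGN effect differed between diets. The vector effect was higher on the HFHC diet for male-biased Hsd3b5 and Slco1a1: Hsd3b5 had an interaction log2 fold change of 10.65 ± 0.93 (SE, edgeR adjusted p = 0.00012), and Slco1a1 one of 3.7 ± 0.45. It was lower for Gstm1, an NRF2 target (-2.09 ± 0.33), Itgax (-3.44 ± 0.57) and H2-Aa (-1.57 ± 0.29). Fga had 1.06 ± 0.19, and Cyp7b1 4.3 ± 0.59.

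By edgeR, 1316 of 12619 genes passed, 687 with a higher and 629 with a lower vector effect on the HFHC diet. Library totals gave 3196, 9.8% higher against 52.2%, with a median shift of -0.28, and the count was 708 without control-diet EGFP replicate 2, 639 and 875 without control-diet hDC-SIGN replicates 1 and 2, and 744 without HFHC EGFP replicate 2.

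For male-biased genes, 5 of 8 tested members had a positive interaction (8 up and 0 down adjusted over the list alone, camera adjusted p = 1.19e-11, adjusted p = 0.0608 with an estimated correlation). For NRF2 targets, 8 of 11 tested members had a negative interaction (0 up and 8 down adjusted over the list alone, camera adjusted p = 6.11e-11, adjusted p = 0.082 with an estimated correlation). In class II genes, 6 of 8 tested members had a negative interaction (0 up and 7 down adjusted over the list alone, camera adjusted p = 6.26e-08, adjusted p = 0.223 with an estimated correlation). In monocyte-derived and lipid-associated macrophage markers, of 15 tested members, 1 had a positive interaction and 7 had a negative one (1 up and 9 down adjusted over the list alone, camera adjusted p = 7.43e-07, adjusted p = 0.214 with an estimated correlation). The member with a positive interaction was Fabp5 (4.3 ± 0.92), a call lost with limma-voom. For acute-phase proteins, 7 of 14 tested members had a positive interaction (9 up and 0 down adjusted over the list alone, camera adjusted p = 9.37e-07, adjusted p = 0.311 with an estimated correlation). For Kupffer cell markers, 1 of 12 tested members had a positive interaction (2 up and 0 down adjusted over the list alone, camera adjusted p = 0.318, adjusted p = 0.733 with an estimated correlation). The median of this list was -0.01 while its mean was 0.4.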

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

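The tests of technical explanations, the counts of other splits and the list of genes checked for a library far from its group were chosen or written down after the results they concern had been seen, while the interaction of diet and vector was planned.

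The vector effect differed between the diets for 1316 genes by the interaction test. At list level, the median interaction log2 fold change was 1.9 for male-biased liver genes, 0.98 for acute-phase proteins, 0.46 for ER stress genes, 0.43 for interferon-stimulated genes and 0.3 for bile acid genes. It was -1.63 for NRF2 targets, -1.61 for class II antigen presentation, -1.32 for monocyte-derived and lipid-associated macrophage markers, -1.18 for the matrix list, -1 for chemokines and -0.97 for dendritic cell markers. It was -0.83 for lipid droplet genes, -0.75 for sinusoidal endothelial markers, -0.71 for stellate cell markers, -0.67 for TLR, NF-kB and inflammasome genes and -0.41 for fatty acid oxidation. Each of these 16 lists passed with the preset correlation, and 0 of the 34 lists passed for the interaction with an estimated one.

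Single genes with a large interaction log2 fold change were Hsd3b5 (10.65), Serpina1e (6.65), Mup12 (6.5), Cyp2b9 (-9.33), Cyp2a4 (-7.11), Gpnmb (-6.35), the glutathione transferase Gsta1 (-4.08) and the carbonyl reductase Cbr3 (-4.05). The fitted values of Moxd1 (15.04) and Xlr4a (11.88) depend on the prior count and are no bounds. Both rest on libraries that differ within a group: Moxd1 had 1048, 1400 and 41 counts in control-diet EGFP replicates 1 to 3 and 0, 2 and 80 in the hDC-SIGN ones. On the HFHC diet it had 2, 2 and 0 counts with EGFP and 399, 1202, 1354 and 2656 with hDC-SIGN. Xlr4a had 43, 70 and 0, then 0, 0 and 0 counts on the control diet, and 1, 6 and 3, then 56, 56, 0 and 27 on the HFHC diet. On the control diet Gpnmb had 4 and 9 counts in all with EGFP and hDC-SIGN, and Cyp2a4 17 and 50.

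Of 81 values checked in the 4 HFHC hDC-SIGN livers, 2 had a library far from the other 3, fewer than the about 1 in 20 that chance gives. Ccl2 stood at 0.343 CPM in replicate 2 against 0.168 to 0.172 CPM in the others, a gap of 0.97 of the range on the log2 scale. That is 6 counts against 3 in each of the others, so the gap rests on very few reads. Lyve1 stood at 9.5 CPM in replicate 3 against 4.34 to 4.57 CPM, a gap of 0.934 of the range.

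With hDC-SIGN on the HFHC diet, 12 of 15 monocyte-derived and lipid-associated macrophage markers fell (adjusted p = 0.0133 with an estimated correlation). So did 8 of 8 class II genes (adjusted p = 0.0772 with an estimated correlation), 12 of 17 matrix genes with 1 rising (adjusted p = 0.113 with an estimated correlation), 9 of 10 stellate cell markers (adjusted p = 0.113 with an estimated correlation) and 7 of 12 Kupffer cell markers with 1 rising (adjusted p = 0.474 with an estimated correlation). These 4 list calls were lost with an estimated correlation, while fry called each list lower. Fry's adjusted p was 0.000199 for class II, 0.000695 for matrix, 0.000765 for stellate and 0.0289 for Kupffer genes. An equal dilution of all RNA from outside hepatocytes is argued against as the whole cause of the macrophage fall. The median was -1.97 for monocyte-derived and lipid-associated macrophage markers and -0.49 for sinusoidal endothelial markers (difference -1.47, 2-sided permutation test over genes, p = 0.017). Some endothelial markers were uneven among the HFHC EGFP livers, such as Oit3 (20.24, 29.95 and 10.75 CPM in replicates 1 to 3), so the -0.49 is uncertain. A smaller dilution shared by endothelial, Kupffer (median -0.72) and stellate (median -0.86) markers was not tested. A loss of all macrophages alike is argued against as the whole cause by the Kupffer cell median of -0.72 (difference -1.24, permutation p = 0.0022). Genes within a list are not independent, and the Kupffer list holds C6, which hepatocytes also express and which rose. A smaller loss shared by all macrophages was not tested. Fewer monocyte-derived and lipid-associated macrophages, or lower expression in as many, may each lie behind the macrophage part and whole-liver RNA cannot separate them, while no cause of the lower class II, matrix and stellate genes was tested.

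With hDC-SIGN, 5 of 8 male-biased liver genes rose on the HFHC diet (adjusted p = 0.0984 with an estimated correlation) and 2 of 8 fell on the control diet (adjusted p = 0.307 with an estimated correlation), so the opposite directions held as list calls with the preset correlation alone. A liver from a female mouse is argued against, since the library with the lowest summed Y-linked CPM stood at 80.9% of the median library (73.1 against 90.4 CPM). A shift of clock or feeding time at harvest cannot be told apart from the vector on the control diet, where clock genes had a median absolute log2 fold change of 0.41 against 0.79 for male-biased genes (permutation p = 0.14), while on the HFHC diet these were 0.14 and 1.5 (permutation p = 0.0022). Exchanged vector labels on the control diet could give such a reversal, but the correlation across genes of the 2 vector effects (-0.07) does not settle it. Against an exchange, Kupffer cell markers had medians of -0.78 on the control diet (adjusted p = 0.333 with an estimated correlation) and -0.72 on the HFHC diet (adjusted p = 0.474 with an estimated correlation). Immediate early genes had -0.65 and -1.37 in that order (adjusted p = 0.428 and 0.113 with an estimated correlation). The 2 values of each list would oppose each other after an exchange. NRF2 targets went the other way, with medians of 0.3 and -1.33 in that order (adjusted p = 0.823 and 0.0772 with an estimated correlation). With hDC-SIGN, 62 genes rose on the HFHC diet and fell on the control diet, where independent lists would share 15.7. The reverse held for 18 (against 19.2), while 29 rose in both (against 13.3) and 20 fell in both (against 22.6). A vector effect may differ by diet and no transgene was measured, so an exchange stays open.

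With hDC-SIGN on the control diet, 5 of 14 acute-phase genes fell, and the list was called lower with the preset correlation but not with an estimated one (adjusted p = 0.342 with an estimated correlation) or by fry (adjusted p = 0.0696). A response in a single EGFP liver is argued against as the whole cause, because the list stayed called lower without each of the 3 EGFP livers in turn (3 of 3, camera adjusted p from 1.08e-14 to 5.1e-08 with the preset correlation). This does not cover a response in 2 livers, since Saa1 stood at 714.8 and 746.9 CPM in EGFP replicates 1 and 2 against 109 CPM in replicate 3, and Saa2 at 724.2 and 462.4 against 30.43 CPM. A response in 2 or all 3 EGFP livers, through handling or infection, was not tested, and whether hDC-SIGN lowers these genes stays open.

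Other splits of the same samples were counted for each comparison. For hDC-SIGN on the HFHC diet, 1 of 35 splits, the real one, gave 2931 genes and the highest other gave 563. Likewise 1 of 35 splits gave 3123 genes for the diet in hDC-SIGN livers, with 367 as the highest other. A chance division of these samples can be excluded at 0.05 for both. For the interaction 1 of 100 drawn gave 1316, with 899 as the highest other. Those splits moved vector labels within each diet, so they tested for any vector effect and not for an interaction alone. They also always kept control-diet EGFP replicate 1 with EGFP, so exchanged control-diet labels were never drawn. No conclusion on the interaction is drawn from them. With 10 splits a share under 0.05 is out of reach: for the diet in EGFP livers the real split gave 5178 genes and the highest other 0, and for hDC-SIGN on the control diet these were 305 and 0.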

How the results depend on the processing

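The list tests under DESeq2 size factors and library totals, and the block by the file's column numbers, were chosen after seeing the data, and the other alternatives were planned. For named genes, 5035 values under other settings kept direction and side of the threshold, 46 gained and 261 lost a call, and 1 reversed: Nr1h3 for hDC-SIGN on the HFHC diet, -0.02 under library totals. Without each library in turn 6469 kept both, 38 gained and 614 lost a call. For lists, 894 kept both under other settings, 25 gained and the rest lost a call, and without each library 2093 kept both, 67 gained and 49 lost a call, with 1 reversed: Erythroid (blood) markers for hDC-SIGN on the control diet, whose signed -log10 camera adjusted p ran from -0.52 to 1.62, the highest without control-diet hDC-SIGN replicate 2 (adjusted p = 0.0239). Requiring a 2-fold change left 1436 genes for diet with EGFP, 894 for hDC-SIGN on the HFHC diet, 73 for hDC-SIGN on the control diet, 606 for diet with hDC-SIGN and 577 for the interaction, by construction. Library totals gave 3196 for the interaction and DESeq2 661 for hDC-SIGN on the control diet, and the cause was not tested. Library totals called 18, 17, 10, 12 and 17 lists against 23, 15, 8, 11 and 16, in that order of comparisons. With an estimated correlation 1, 1, 0, 0 and 0 lists were called in that order of comparisons. Fry called 25, 16, 0, 11 and 10, and the cause of these differences was not tested.

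Leaving out 1 library gave 3867 to 5281 genes for diet with EGFP, 1614 to 3151 for hDC-SIGN on the HFHC diet, 9 to 416 for hDC-SIGN on the control diet, 1787 to 3252 for diet with hDC-SIGN and 639 to 1439 for the interaction. The lowest value for hDC-SIGN on the HFHC diet was without HFHC EGFP replicate 2, that for hDC-SIGN on the control diet and the interaction without control-diet hDC-SIGN replicate 1, and that for diet with hDC-SIGN without control-diet hDC-SIGN replicate 2. Called lists ranged from 16 to 24, 16 to 20, 7 to 9, 10 to 13 and 12 to 17, and the correlation of diet and vector effects from -0.81 to -0.75. Replicate numbers from the sample titles showed no pairing: same-number deviations correlated at -0.19 to 0.08 over 18 pairs, and 2 of the 12 libraries with a partner correlated best with their own number. With the number as a block, 4949, 2367, 224, 2418 and 1061 genes and 24, 15, 9, 11 and 15 lists were called. That block called monocyte-derived and lipid-associated macrophage markers lower for hDC-SIGN on the control diet, as library totals did, and clock genes for diet with EGFP and the interaction. It did not call ER stress genes or TLR, NF-kB and inflammasome genes for the interaction. The file's column numbers call the third control-diet library of each vector 4, and by these numbers 16 pairs also gave -0.19 to 0.08, with 2 of 13 libraries best correlated with their own number. As a block they gave 4260, 2342, 59, 2335 and 888 genes and 24, 15, 9, 12 and 16 lists, so hDC-SIGN on the control diet had 59 genes against 305 without a block.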

Other observations

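The gene families named by symbol stem were tested after the data were seen, while the gene lists were planned, and no hypothesis is added here.

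Lymphocyte markers were scarce. Among T and NK cell markers for the diet in EGFP livers, 3 of 4 tested members rose (3 up and 0 down adjusted over the list alone, camera adjusted p = 0.107, adjusted p = 0.392 with an estimated correlation). Cd8a changed by 2.6 ± 0.5 and Nkg7 by 2.06 ± 0.46, from 8 and 13 counts in all in the control-diet livers. With hDC-SIGN on the HFHC diet, of 4 tested members, 1 rose and 2 fell (1 up and 2 down adjusted over the list alone, camera adjusted p = 0.432, adjusted p = 0.665 with an estimated correlation). Cd8a and Nkg7 fell by 1.58 and 1.91 on the log2 scale, the call of Cd8a being lost without HFHC EGFP replicate 2, and Cd4 rose from 0.794 ± 0.0553 to 2.28 ± 0.944 CPM. For B and plasma cell markers in that comparison, 1 of 5 tested members fell (0 up and 1 down adjusted over the list alone, camera adjusted p = 0.298, adjusted p = 0.561 with an estimated correlation). For cholangiocyte markers, 0 of 4 tested members passed by edgeR, 1 at an unadjusted p under 0.05 and 0 by DESeq2 (0 up and 0 down adjusted over the list alone, camera adjusted p = 0.65, adjusted p = 0.867 with an estimated correlation). Among cytokines and mediators for the diet in EGFP livers, 1 of 3 tested members rose (1 up and 0 down adjusted over the list alone, camera adjusted p = 0.297, adjusted p = 0.501 with an estimated correlation). The adipsin gene Cfd, also an adipocyte marker, rose with the diet in hDC-SIGN livers from 0.136 ± 0.145 CPM, 7 counts in all, to 35.7 ± 39.7 CPM (7.97 ± 2.02), a call lost with limma-voom and without control-diet hDC-SIGN replicate 2.

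Among clock genes for the diet in hDC-SIGN livers, of 11 tested members, 2 rose and 3 fell (2 up and 3 down adjusted over the list alone, camera adjusted p = 0.907, adjusted p = 0.998 with an estimated correlation). Per3 changed by 1.04 ± 0.18 and Dbp by 0.82 ± 0.17. For glucose metabolism with hDC-SIGN on the HFHC diet, 1 of 10 tested members fell (0 up and 1 down adjusted over the list alone, camera adjusted p = 0.65, adjusted p = 0.867 with an estimated correlation), and the insulin-sensitive gene Igfbp1 went from 60.1 ± 28.9 to 15 ± 7.78 CPM (-2 ± 0.44). Among pericentral hepatocyte genes for the diet in EGFP livers, of 8 tested members, 1 rose and 2 fell (1 up and 2 down adjusted over the list alone, camera adjusted p = 0.233, adjusted p = 0.559 with an estimated correlation). Cyp1a2 changed by -1.06 ± 0.19 and Glul, a glutamine synthetase, by 0.54 ± 0.14. For xenobiotic P450 genes in that comparison, of 10 tested members, 1 rose and 3 fell (1 up and 3 down adjusted over the list alone, camera adjusted p = 0.2, adjusted p = 0.559 with an estimated correlation). For erythroid markers, 1 of 5 tested members fell (0 up and 1 down adjusted over the list alone, camera adjusted p = 0.313, adjusted p = 0.617 with an estimated correlation).

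Mup genes, 20 tested as a family of major urinary proteins, had a median log2 fold change of 2.64 with hDC-SIGN on the HFHC diet, where 19 rose (camera adjusted p = 4.09e-19 over 203 families, adjusted p = 0.372 with an estimated correlation). On the control diet the median was -1.51 and 3 fell (camera adjusted p = 5.14e-12, adjusted p = 0.96 with an estimated correlation). These counts are uncertain because the copies are nearly identical. Of 48 Rpl ribosomal protein genes, 23 fell with the diet in EGFP livers and the median was -0.25 (camera adjusted p = 0.00057, adjusted p = 0.557 with an estimated correlation). Library totals moved the median of all genes by 0.28 in that comparison, so these 23 calls may depend on the scaling. The family was not tested under library totals. In hDC-SIGN livers, where that shift was 0.01, 26 fell with the diet and the median was -0.24 (camera adjusted p = 3.74e-06, adjusted p = 0.816 with an estimated correlation).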
